A study of Mus musculus with 12 samples.

How the data were processed

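RNA was measured in 12 libraries of mouse atrioventricular node (the tissue that passes the heartbeat from atria to ventricles with a delay). Per the labels' protocols, the nodes came from FVB/NJ pups at neonatal day 8 or 10, were found by the green fluorescence of a Tbx3 reporter transgene, and were cut out by laser from 5 consecutive sections of 8 µm. RNA of about 300 to 2000 pg was turned into amplified cDNA with a NuGEN Ovation V2 kit and sequenced on a HiSeq4000. The groups were taken from the library titles: 6 wild-type libraries (WT 1 to WT 6) and 6 libraries from pups heterozygous for a Tbx3 allele that carries CreERT2 (heterozygous 2 to 7). The labels do not say that each library came from a different pup. If some shared a pup or litter, the p-values given here measure in part a technical spread and are too small. The node was found by the fluorescence of a Tbx3 transgene, so the choice of tissue and the level of Tbx3 are not independent.

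The deposited table holds 41128 genes. Per the submitters' processing notes, reads were aligned with STAR to mm10 and normalised with DESeq2. The versions, the counting tool, the strand setting and the annotation are not given in the sources used here. The values are a signal per gene that the authors made by dividing read counts by 1 size factor per library. In every library 100% of the values above 0.1 were whole multiples of the smallest one, within a tolerance of 0.001, so whole reads could be recovered, and the size factors computed from those reads by the median of ratios matched the deposited scale. The authors wrote 0 as 0.1, which was set back to 0. Gene symbols were taken by Ensembl identifier from a reference table that matched 40254 of the identifiers (97.9%). Coordinates are those of GRCm38 (mm10). Because the counting is not stated to use strand, reads of overlapping or antisense genes cannot be told apart, and near-identical copies such as Hba-a1 and Hba-a2 are uncertain.

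Genes with a mean of at least 10 over the 12 libraries (15899) were tested with limma 3.58.1 in R 4.3.3, with the trend option, on log2(value + 1). A fold change on this scale understates that of low genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The genotype fit had no other term, the age fit (day 10 minus day 8) kept genotype as a term, and the interaction was fitted with both. Tbx3 and the listed genes that passed were also tested by exact permutation of the libraries. A total of 30 gene lists with 410 genes was fixed before the data were examined, covering conduction and chamber genes, contraction, metabolism, the cell cycle, signalling, stress and markers of other heart cell types. Lists with at least 3 tested members (29) were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Listed genes were adjusted over all genes and over the list alone. Named genes followed a rule fixed at the same time. By genotype it takes Tbx3, up to 10 higher and 10 lower genes past the threshold with a mean of at least 50 and an official name, and up to 4 members of each list, first those past the threshold and, where fewer than 2 pass, those with the smallest p up to 2. By age it takes up to 5 higher and 5 lower genes and up to 3 members of each list, all past the threshold, and for the interaction up to 5 genes. A few genes that the rule takes are not described. Xist and the Y-linked genes serve only as a check of sex balance. No gene passed by age or in the interaction over all genes, so every gene named there was chosen after its values were seen.

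Counts were simulated for the real genes, each gene drawn independently. In them 100 genes were changed 2-fold and 100 were changed 4-fold, all with a mean of at least 50, so lower genes were not tried. The genotype fit called 23% of genes changed 2-fold and 79% of those changed 4-fold. It made 5 false calls, with 15392 genes tested, the changed ones included. The age fit called 18% and 72%, with 5 false calls and 15385 genes tested. The alternatives were another pseudocount, filter, scaling or threshold, an age term, a Y-linked term, a block on the replicate number, library weights, 1 age only, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Chosen after seeing the data were voom, keeping 0.1, leaving out the 2 libraries least like the others, terms or subsets by the share of mitochondrial reads, and some of the tests of explanations in the closing part. Figures were drawn with matplotlib 3.10.9.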

Results

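Gene expression was measured in laser-captured atrioventricular nodes of wild-type pups and of pups with 1 modified Tbx3 allele. Tbx3 is a T-box transcription factor of the conduction system, and the comparison asks which node transcripts depend on its full dose. Each genotype had 6 libraries. At day 8 there were 4 wild-type and 3 heterozygous libraries, and at day 10 there were 2 and 3. Libraries held between 18974142 and 29983630 reads in genes, with a mean of 23914816 ± 3003600 (SD, n = 12). The value of 1 read lay between 0.555 and 1.73 normalised counts, so that 3 reads correspond to at most 5.19.

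Mitochondrial transcripts took a large and uneven share of the reads, from 36.3% to 72.0%. Most of these were mitochondrial ribosomal RNA (mt-Rnr1 and mt-Rnr2), with a mean of 45.9% of reads against 53.5% for all mitochondrial transcripts. The whole mitochondrial share was 51.5% ± 6.94 in wild type and 55.5% ± 13.2 in heterozygotes (SD, n = 6 each, two-sided exact permutation p = 0.524). At day 8 it was 48.2% ± 8.52 (n = 7) and at day 10 60.9% ± 8.01 (n = 5; exact permutation p = 0.0290). WT 1, WT 2, heterozygous 2 and heterozygous 3, all of day 8, had under 50%, and the other 8 libraries, 3 of them of day 8, had over 50%. The size factors of these 4 lay between 1.31 and 1.80 and those of the other 8 between 0.578 and 0.984; the labels give no batch. The first principal component (16.6% of the variance) set heterozygous 7 apart and the second (14.4%) WT 3. These libraries also had the lowest median correlations with the others, 0.805 and 0.813. Xist was at 32214 normalised counts or more in 8 libraries and the Y-linked genes were high in WT 1, WT 4 and heterozygous 4.

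**Figure D1:**
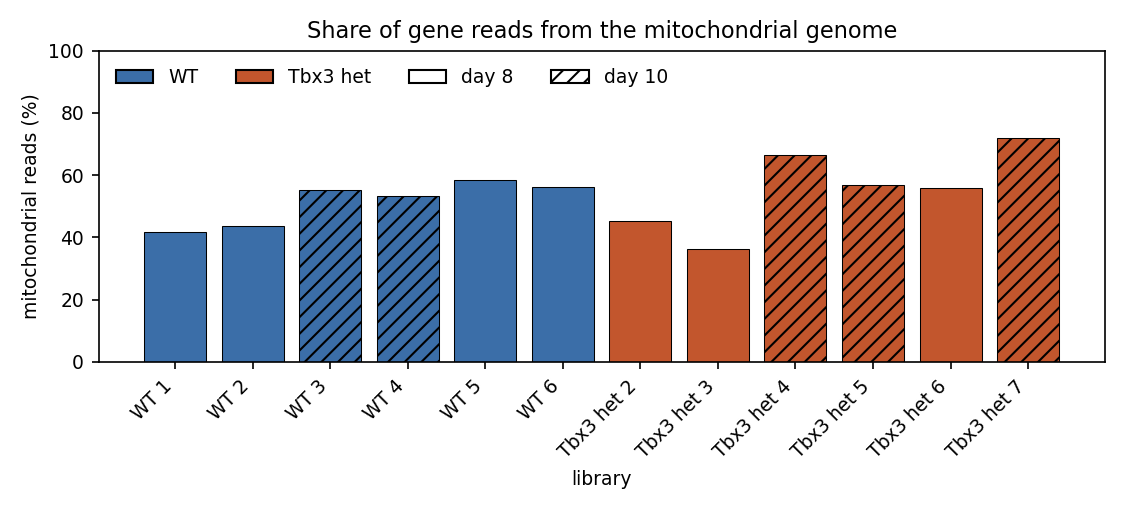
Share of reads in genes that came from the mitochondrial genome, in percent, for each of the 12 libraries; colour gives the genotype and hatching day 10. The 5 day 10 libraries lie between 53.3% and 72.0%, and 4 of the 7 day 8 libraries lie under 50%.

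Tbx3 itself (ENSMUSG00000018604, chromosome 5, 119670669 to 119684724 in mm10) was at 6304 ± 1343 normalised counts in wild type and 5860 ± 1409 in heterozygotes (SD, n = 6 each). Its log2 difference of −0.11 ± 0.19 (SE) was smaller than the spread between libraries (limma, adjusted p = 0.985; exact permutation p = 0.587, where the smallest possible is 0.00216), with a 95% interval from −0.51 to 0.28. In single libraries it ran from 4357 to 7924 in wild type and from 3862 to 7777 in heterozygotes. The interval excludes a halving of the signal, but a count per gene cannot tell reads of the modified allele, or of a transgene, from those of the intact allele, so Tbx3 does not check the labels here. The difference was 0.08 among day 8 libraries and −0.35 among day 10 libraries (interaction −0.43 ± 0.38, SE). It was 0.38 in the 4 libraries under 50% mitochondrial reads and −0.36 in the other 8.

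Among the listed genes that passed the test of genotype adjusted over their list alone were Ryr2, Kcne1, Hcn4 and Cacna2d2, which encode ion channels or channel subunits. Ryr2 (chromosome 13, 11553102 to 12106945), the calcium release channel of the sarcoplasmic reticulum, was at 7923 ± 1411 in wild type and 14222 ± 1579 in heterozygotes, a log2 difference of 0.85 ± 0.15 (SE), and all 6 heterozygous libraries lay above all 6 wild-type ones. Kcne1 (chromosome 16, 92345982 to 92359468), a potassium channel subunit, was higher as well, with 1255 ± 285 against 2205 ± 555, a log2 difference of 0.81 ± 0.20 and again no overlap. Hcn4 (chromosome 9, 58823412 to 58863175), the main pacemaker channel, was lower, with 2475 ± 1038 against 1074 ± 438, a log2 difference of −1.20 ± 0.28 and 6 of 6 heterozygous libraries below the wild-type mean, and Cacna2d2, a calcium channel subunit, was at 11137 ± 3244 against 6613 ± 2483, a log2 difference of −0.80 ± 0.25.

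None of the 15899 genes passed the threshold over all genes. The smallest adjusted p was 0.198, for Ryr2. With limma 853 genes had an unadjusted p under 0.05 (460 higher and 393 lower in heterozygotes), where chance gives 795. edgeR called 0 genes and DESeq2 7, of which 6 were higher. With age as a term Ryr2 passed (adjusted p = 0.0428), and it also passed without WT 3 (0.0494). Over all alternatives its adjusted p ran from 5.80e-04 with DESeq2, where it was among the 7 called, to 0.991 at day 10 only. That subset holds 5 libraries. With all 12 libraries and the replicate block it was 0.954. For 36 genes the 6 heterozygous values lay all on one side of the wild-type values, 0.226% of the genes tested against 0.216% by chance.

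Adjusted over the list alone, 7 listed genes passed, of which 6 are described here: Ryr2 (adjusted p = 1.99e-04), Hcn4 (0.00674), Kcne1 (0.00626 among the ventricular markers), Lyz2 (0.0117), Scx (0.0258) and Cacna2d2 (0.0408). Over all listed genes at once only Ryr2 passed (adjusted p = 0.00438). Exact permutation gave p = 0.00216 for Ryr2 and for Kcne1, the smallest possible, 0.00866 for Hcn4, 0.00649 for Lyz2, 0.00433 for Scx and 0.0346 for Cacna2d2. It was run on genes that had already passed on the same values, so these p-values are no independent support. Lyz2, a lysozyme of macrophages, was lower in heterozygotes (626 ± 241 against 238 ± 108), and Scx, a tendon and valve transcription factor, was higher, with wild type near the floor (4.50 ± 4.64 against 35.4 ± 29.9). In the 8 libraries over 50% mitochondrial reads the log2 differences were −1.70 for Hcn4, −1.21 for Cacna2d2, 0.88 for Ryr2, 0.71 for Kcne1, 3.48 for Scx and −2.02 for Lyz2. In the 4 libraries under 50% they were, in the same order, −0.19, 0.03, 0.80, 1.01, 2.07 and −0.44, with 2 libraries per genotype and no exact p under 0.333 possible. These sets were chosen after seeing the data. The 7 genes were 4 without heterozygous 4. Cacna2d2 no longer passed without WT 4, WT 5, WT 6 or heterozygous 4, 5 or 6, and Scx without WT 1, WT 3, WT 5 or heterozygous 4 or 7.

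**Figure D2:**
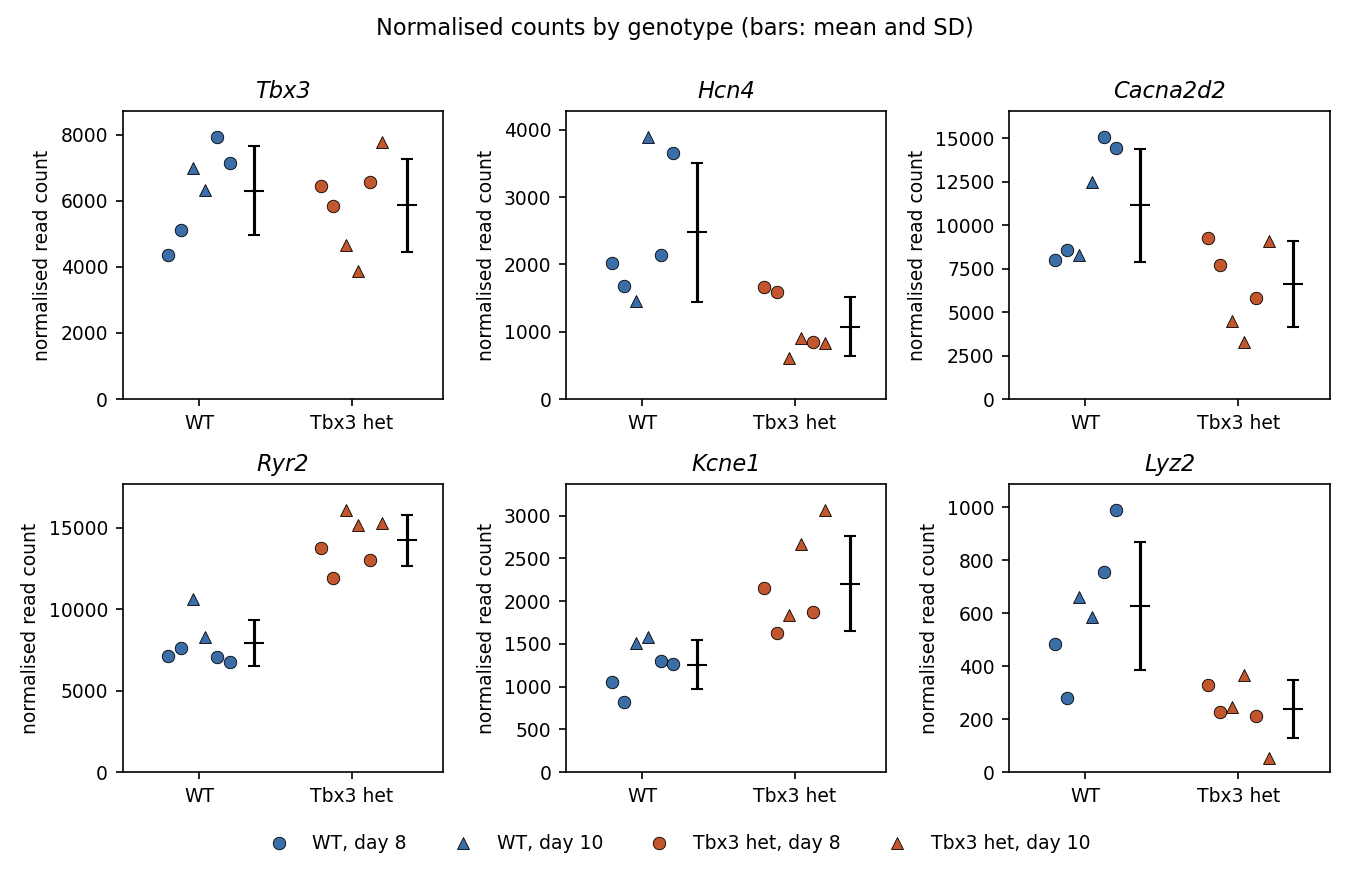
Normalised read counts (linear axes from 0) of 6 genes per library by genotype; each point is a library, shaped by age, and the bars show the mean and SD over 6 libraries. Ryr2 and Kcne1 do not overlap between genotypes, Hcn4 and Cacna2d2 are lower on average in heterozygotes with overlap, as is Lyz2, and Tbx3 shows no separation.

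Gene lists were compared with camera at the preset correlation. The nodal list fell in heterozygotes: 16 of its 18 tested members were lower, with a median log2 difference of −0.42 (adjusted p = 1.57e-05). With an estimated correlation the adjusted p was 0.285. Hcn4 and Cacna2d2 were the members past the threshold adjusted over the list alone. In the 4 libraries under 50% mitochondrial reads the list did not pass, with a mean of −0.14 and the camera direction reversed. In this list Gjc1, a gap junction gene of the node, differed by −0.44. The sarcomere list rose (18 of 24 higher, median 0.18, adjusted p = 0.00131), and its adjusted p with an estimated correlation was 0.596. None of its members passed alone. Myh6, the alpha myosin heavy chain, differed by 0.42 and Myl2, the ventricular light chain, by 0.49. The ventricular myocyte markers rose (7 of 9, adjusted p = 0.0370, and 0.596 with an estimated correlation). Of these Kcne1 alone passed over the list. The smooth muscle and pericyte markers rose too (10 of 13, adjusted p = 0.0398, and 0.875 with an estimated correlation). There Lmod1 differed by 2.85 at a low level and Acta2 by 0.42. Myl2, Myl3 and Myh7 are in both the ventricular and the sarcomere list, and Des in both the smooth muscle and the sarcomere list. The 3 results are thus not fully separate. In the 4 libraries under 50% mitochondrial reads the mean of the smooth muscle and pericyte list was −0.19. The mitochondrially encoded transcripts rose (13 of 13, adjusted p = 0.0376, and 0.875 with an estimated correlation). Among these mt-Cytb differed by 0.34 and mt-Atp8 by 0.42, and the list mean was −0.35 among day 8 libraries alone. Heterozygous 4 and heterozygous 7 had the highest mitochondrial shares of reads, 66.5% and 72.0%. Fibroblast and matrix markers fell (13 of 16 lower, adjusted p = 0.0390, and 0.875 with an estimated correlation), with Lum at −0.61 and Dcn at −0.44. The mean of this list was 0.046 in the 8 libraries over 50% mitochondrial reads. No list passed with an estimated correlation or with fry, directional or mixed. The count of 6 lists was 1 without WT 2, 2 without heterozygous 7 and 3 without heterozygous 4 or heterozygous 5.

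The other 23 lists did not pass, with adjusted p from 0.0792 to 0.935. Conduction transcription factors had 13 of 19 members lower (adjusted p = 0.178), among them Hand1 at −2.37 and Nkx2-5, a cardiac homeobox factor, at −0.73. Chamber myocardium genes were split 10 to 10 (adjusted p = 0.935). There Kcnj2, the inward rectifier channel, differed by −1.07. The atrial markers (adjusted p = 0.886) held Stard10 at −0.78 and Nr2f2 at 0.50. The His-Purkinje list (adjusted p = 0.738) held Kcne1. Calcium handling genes (adjusted p = 0.482) held Ryr2 and, in the other direction, Slc8a1, the sodium-calcium exchanger, at −0.29. The gap junction and adhesion list (adjusted p = 0.886) held Pkp2, a plaque protein of the intercalated disc, at 0.56. Of the metabolic lists, nuclear oxidative phosphorylation genes (adjusted p = 0.738) held Atp5c1 at 0.42 and Ndufb5 at 1.37, and fatty acid oxidation genes (adjusted p = 0.487) held Echs1 at 1.00 and Hadha at 0.31. Cell cycle genes had 16 of 24 members lower (adjusted p = 0.148), with Ccnb2 at −1.63 and Mcm2 at −0.74. Signalling genes (adjusted p = 0.114) held Wnt5a at −1.08 and Hey1 at −0.94, fetal growth genes (adjusted p = 0.738) Meg3 at 0.61 and Lin28b at 1.13, early response genes (adjusted p = 0.886) Btg2 at −0.79 and Gadd45b at 1.77, and interferon response genes (adjusted p = 0.502) Oasl2 at 2.13. Ryr2 and Kcne1 passed over the calcium handling and His-Purkinje lists alone. The genes given here with a log2 difference did not pass over all genes or over their lists.

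Markers of other cell types did not pass as lists either: endothelium (8 of 11 higher, adjusted p = 0.0792, Flt1 at 0.53 and Pecam1 at 0.38), endocardium (0.886, Vwf at 1.80 and Hapln1 at −1.32), valve interstitial cells (0.811, Scx above and Vcan at −0.31), macrophages (0.738, Lyz2 above and Cx3cr1 at 0.57), lymphocytes and granulocytes (0.886, Cd79a at 0.50 and Cd4 at 0.37), red cells (0.487, Hba-a2 at 0.34 and Hba-a1 at 0.27), autonomic neurons (0.738, Nefl at 1.90 and Stmn2 at −0.70), Schwann cells and glia (0.465, S100b at −1.79 and Cnp at −0.63) and epicardium (0.886, Aldh1a2 at −0.48 and Wt1 at 0.89). The values in brackets are camera adjusted p and log2 differences. Of the adipocyte list 1 gene was tested, Fabp4 at 0.32. The sex-linked list had an adjusted p of 0.886. The median and the camera direction had opposite signs in the chamber, His-Purkinje, atrial and fetal growth lists, and the mean and the camera direction in the chamber, early response and epicardium lists.

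**Figure D3:**
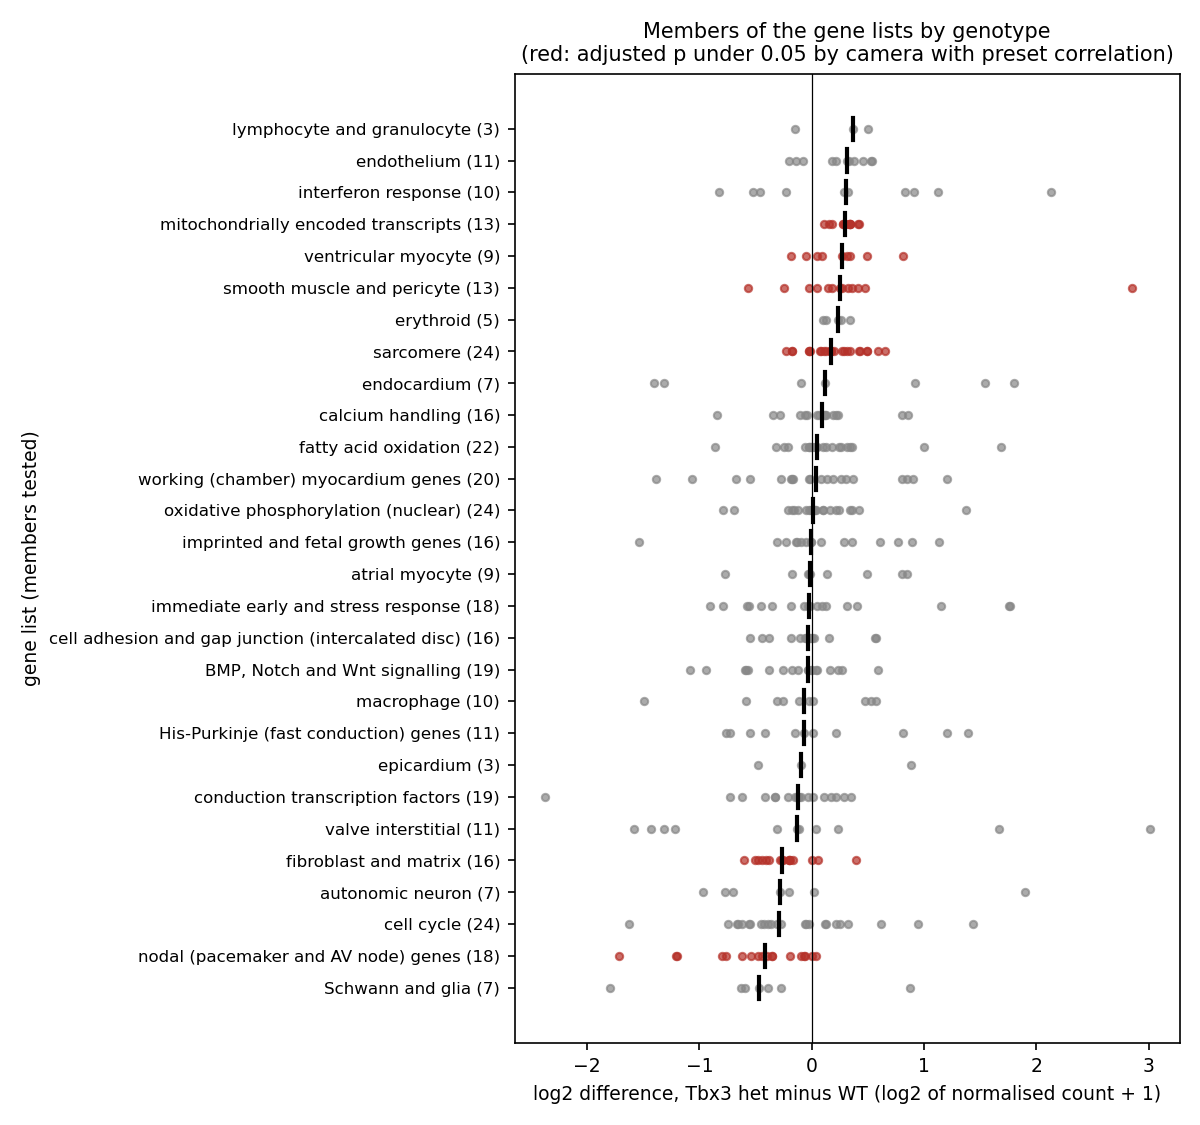
Log2 difference between heterozygous and wild-type libraries for each tested member (points) of 28 gene lists, with the list median as a black bar; members tested are in brackets and red marks an adjusted p under 0.05 with the preset correlation. The nodal list has 16 of 18 members below 0 and its median at −0.42.

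The second comparison was of age, day 10 against day 8, with genotype as a term. Tnni1, the fetal troponin I, was lower at day 10 (1205 ± 185, n = 7, against 522 ± 224, n = 5; log2 difference −1.31 ± 0.26), with no overlap between the ages. The proliferation genes Top2a and Rrm2 were lower too, at −0.95 and −2.56. Col1a1, a fibrillar collagen, differed by 1.22 (23195 ± 13708 against 47389 ± 17520), Prg4, the lubricin of joint surfaces, by 2.66, Rgs5, a pericyte gene, by 0.65, and Atp5o, an ATP synthase subunit, by 0.72. These genes were chosen after their values were seen. None passed over all genes (smallest adjusted p = 0.0536, Zc3h13); 1856 had an unadjusted p under 0.05, 842 higher and 1014 lower. edgeR called 0 and DESeq2 206, where DESeq2 gave no adjusted p for 7418 of the 15899 genes and so adjusted over fewer. Without heterozygous 7 limma called 10, and among genes with a mean of at least 50 it called 9. Adjusted over the list alone 26 listed genes passed, and 16 over all listed genes at once, among them Tnni1, Col1a1, Prg4, Top2a, Rrm2 and Atp5o. The count of 26 was 15 without heterozygous 2, 17 without WT 3, heterozygous 4 or heterozygous 6, and 44 without heterozygous 7. With any 1 library left out 11 of the 26 passed every time, namely Tnni1, Prg4 and 9 mitochondrially encoded genes. Leaving out 1 library cannot test the 4 libraries under 50% mitochondrial reads, all of day 8, as a set. Top2a no longer passed without WT 2, WT 3 or heterozygous 2, 6 or 7, Rrm2 without WT 2, WT 3 or heterozygous 6 or 7, Col1a1 without WT 3, and Atp5o without heterozygous 2. Rgs5 was lost without WT 3, WT 5 or heterozygous 2, 4, 5, 6 or 7, and Col1a2 and Lum without WT 3, WT 5, WT 6 or heterozygous 2, 4, 5 or 6. Exact permutation gave p = 0.00126 for Tnni1, the smallest possible, 0.0227 for Col1a1, 0.00631 for Prg4 and 0.00758 for Top2a. It gave p under 0.05 for 23 of the 26 genes, and 0.0758 for Col1a2, 0.111 for Lum and 0.0682 for Col6a3. This permutation moved libraries without regard to genotype, which the limma fit kept as a term, so the 2 tests differ. The 26 genes were picked by the limma test on the same values, so small permutation p-values are no independent support.

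**Figure D4:**
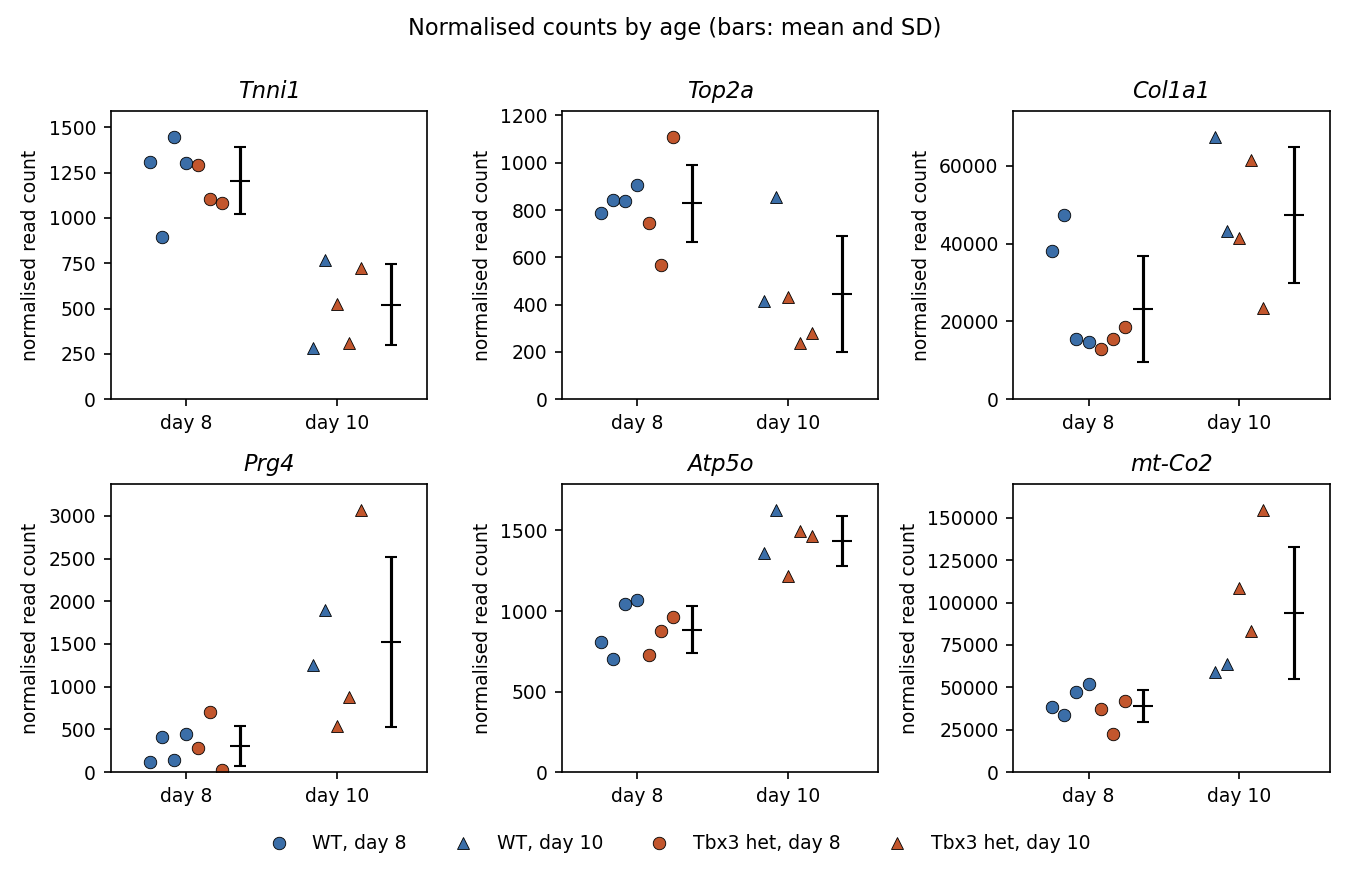
Normalised read counts (linear axes from 0) of 6 genes per library at day 8 (7 libraries) and day 10 (5 libraries), chosen after their values were seen; colour gives the genotype and the bars the mean and SD. Tnni1, Atp5o and mt-Co2 do not overlap between the ages.

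By age 4 lists passed with the preset correlation. The mitochondrially encoded transcripts rose at day 10 (13 of 13 higher, median 1.00, adjusted p = 2.84e-16), and 12 of these passed over the list alone, with mt-Co2 at 1.19 and mt-Nd4l at 1.82. The cell cycle list fell (21 of 24 lower, median −0.53, adjusted p = 2.53e-04). Fibroblast and matrix markers rose (14 of 16, median 0.58, adjusted p = 1.04e-06), with Col1a2 at 1.01 and Lum at 0.82, and smooth muscle and pericyte markers rose (11 of 13, median 0.44, adjusted p = 1.21e-04). With an estimated correlation the adjusted p was 0.445, 0.479, 0.479 and 0.445 in the same order, and none passed with the directional test of fry. The mixed test of fry, for change in either direction, called the nuclear oxidative phosphorylation list (adjusted p = 0.0103). The other 25 lists had adjusted p from 0.0528 to 0.693, and in the early response list the mean had the opposite sign of the median and the camera direction. The mitochondrial share of reads differed between the ages in the same direction as its list, 48.2% at day 8 and 60.9% at day 10. The 4 libraries under 50% were all of day 8. Among the 8 libraries over 50%, 5 of them of day 10, 8 lists passed. Of the 13 mitochondrially encoded genes, mt-Co2 and mt-Nd4l passed over the list alone in these 8. The list's mean log2 value was 15.70, 15.75 and 15.58 in WT 5, WT 6 and heterozygous 6, of day 8. At day 10 it was 15.91 and 15.75 in WT 3 and WT 4, and 16.64, 16.11 and 17.18 in heterozygous 4, 5 and 7. In the comparison of all libraries the count of 4 was 9 without WT 1 and 9 without heterozygous 7.

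The interaction asks whether the genotype difference itself differed between the ages. No gene passed in limma (867 at an unadjusted p under 0.05, smallest adjusted p = 0.523, Cdh20) or in edgeR, and DESeq2 called 20. Adjusted over the list alone 9 of the 13 mitochondrially encoded genes passed, such as mt-Co2 with an interaction of 1.23 ± 0.38 (SE, log2). The mitochondrial share was 50.04% ± 8.44 and 54.4% ± 1.45 in wild type at day 8 and day 10 (n = 4 and 2) and 45.8% ± 9.78 and 65.2% ± 7.58 in heterozygotes (n = 3 each). None of these 9 genes passed over the list alone without heterozygous 3 or without WT 4.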

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

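Several tests were chosen after the results were seen. These were the tests of mitochondrial share and of the Y-linked term for Hcn4 and Ryr2, and of Hcn4 against other nodal genes. They also include the split counts of genes at an unadjusted p and the splits that keep the ages. By age they include the split counts of genes over their list alone and of the smallest p of a gene or list. Ryr2, Hcn4 and the nodal list were themselves picked from the results. They had the smallest p by genotype of all genes, of the nodal genes and of the lists. Every test that names them therefore followed the results. Between genotypes, 100 of the 462 possible splits of the libraries into 6 and 6 were drawn, the real one included, and 31 gave as many genes at an unadjusted p under 0.05 as the real split (853, highest of the others 1395), 26 as many genes past the threshold over their list alone (7, highest other 39) and 33 as many lists (6, highest other 14). Chance therefore cannot be excluded for these counts. For the nodal list taken by itself 1 split, the real one, gave so small a p (−log10 p of 6.27, highest other 6.22), but 47 splits gave some list with a p as small (highest other 20.1), so over all lists chance cannot be excluded. A listed gene with a p as small as that of Ryr2 came up in 1 split, the real one (−log10 p of 4.91, highest other 4.90), which speaks against chance for Ryr2, by a narrow margin. These splits differ in how they part the ages. Among 100 of the 350 splits that keep 3 libraries of each age in the heterozygous group, 20 gave as many genes at an unadjusted p (highest other 1280), 15 as many over their list alone (highest other 22) and 26 as many lists (highest other 11), so chance cannot be excluded there either. A p as small for the nodal list came up in 4 of them (highest other 7.18), for some list in 29 (highest other 14.8) and for a gene as for Ryr2 in 1, the real one (highest other 4.90). Among the splits drawn without regard to age, some gene passed over all genes in 6 of 100, about as often as the threshold allows by chance, with at most 16 genes in a split where the real one has 0.

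Between ages 1 of 100 drawn splits into 7 and 5, the real one, gave as many genes at an unadjusted p under 0.05 (1856, highest other 1754), which argues against chance for that count alone, by a narrow margin. As many genes past the threshold over their list alone came up in 6 (26, highest other 50) and a listed gene with as small a p in 6 (−log10 p of 4.59 for mt-Nd4l, highest other 6.00), so chance cannot be excluded for the 26 genes. As many lists came up in 45 (4, highest other 12) and a list with as small a p in 7 (17.0 for the mitochondrially encoded transcripts, highest other 21.8), so chance cannot be excluded for the lists.

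Hcn4 was lower in heterozygotes. If less nodal tissue had been captured, the other 17 nodal genes and Tbx3 would be lower by as much; the genotype difference of log2 Hcn4 minus their mean was −0.75, with a 95% interval from −1.37 to −0.12, but this excludes nothing, since Hcn4 was the member with the smallest p in the same values and Tbx3 guided the capture, so that less nodal tissue stays open. Ventricular muscle in the captured area (Hcn4 difference −1.19 with Myl2, Myl3 and Irx4 as a term), unequal numbers of males and females (−1.21 with a Y-linked term) and mitochondrial share (−1.10 with that term) left the difference within 1 SE (0.33) of −1.20. The genotype difference was nonetheless smaller in the 4 libraries under 50% mitochondrial reads than in the other 8, by 1.52 (95% interval 0.26 to 2.78), a split made after seeing the data that also parts the libraries by size factor and holds day 8 alone on one side. A lower dose of Tbx3 stays open as well and was not tested.

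Ryr2 was higher in heterozygotes by 0.85. With the mean of the sarcomere list as a term it was 0.81, with the mitochondrial share 0.81 and with the Y-linked term 0.86, all within 1 SE (0.12), which argues against each of the 3 as the whole cause. The sarcomere mean counts muscle of any kind, so less nodal tissue beside neighbouring muscle was not tested and stays open for Ryr2, as for Hcn4. The genotype, or anything that goes with it such as litter, also stays open and untested.

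The 14 listed genes outside the mitochondrial genome that passed by age over their list alone had a median absolute log2 difference of 1.01. With the mitochondrial share as a term the median was 1.30, a ratio of 1.29, and all 14 kept their direction, which argues against the share as the cause of the median difference. The 14 are not independent: 5 are fibroblast and matrix markers, a list whose members moved together (estimated correlation 0.71). A further 3 are smooth muscle and pericyte markers (Mylk, Pdgfrb and Rgs5), and 1 is a valve marker (Prg4). With the term 10 of the 14 still passed over their list alone. Atp5o (0.72 without and 0.59 with the term), Rrm2 (−2.56 and −2.49) and Top2a (−0.95 and −1.01) no longer passed at about the same difference, and Slc25a20 no longer passed as its difference went from −1.47 to −0.63, so that the share stays open for Slc25a20. Litter or collection day may go with age and is not given in the labels, so it stays open, as does chance by the splits above, and growth between day 8 and day 10 stays open and untested. The lower depth of day 10 libraries outside the mitochondrial genome was not tested as a cause and stays open. Fibroblast and smooth muscle marker lists rose by age with the preset correlation and did not pass with an estimated one. Whether a changed mix of cell types in the captured tissue lies behind the differences of the 14 genes was not tested and stays open.

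The following values lay far from the rest of their group by Dixon's test at the 95% level, which chance alone gives in about 7.3 of the 146 groups looked at; there were 8. Atp5c1 was 732 in WT 5 (next 1007). Pkp2 was 6544 in heterozygous 7 (next 2524), and Lyz2 was 55.3 in the same library (next 211). Cd79a, a B-cell gene, was 24.1 in WT 2 (next 1.14) and 208 in heterozygous 3 (next 1.03). The same 2 libraries had the most genes detected, 25008 in WT 2 (next 20538) and 27520 in heterozygous 3 (next 20972). WT 3 had a median correlation of 0.813 with the other libraries (next 0.841). The genotype difference of 3 mitochondrial genes differed between the ages, by an interaction of 1.23 for mt-Co2, 1.18 for mt-Atp8 and 1.14 for mt-Cytb, past the threshold over the list alone and not over all genes. None of the 3 passed over the list alone without WT 4 or without heterozygous 3.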

How the results depend on the processing

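Subsets and terms by mitochondrial share, voom, keeping 0.1 and leaving out WT 3 and heterozygous 7 together were chosen after the data were seen. Of 2549 values of named genes and lists under all alternatives, 2418 kept direction and side of the threshold, 72 lost the call, 22 gained one and 37 reversed. No gene passed over all genes in the main fits, so a gene value could not lose a call. The 72 lost calls were therefore all of lists, and the 2418 do not measure how stable the calls are. Where no cause is given, the cause was not tested. All planned settings ran; edgeR and DESeq2 gave no list test.

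Genes called by genotype (0) were 1 with quantile normalisation, the age term, voom, and age and mitochondrial terms together (Ryr2 each time), 1 in the 8 libraries over 50% mitochondrial reads (Itga9), 7 with DESeq2 and 9 in the 4 libraries under 50%. Leaving out 1 library gave 0 to 1, the 1 being Ryr2 without WT 3. Over the other settings the adjusted p of Ryr2 ran from 5.80e-04 (DESeq2) to 0.991 (day 10 only). That of Hcn4 ran from 0.0561 (DESeq2) to 0.995 (without heterozygous 4). Listed genes past the threshold over their list alone (7) were 2 at day 8 only (Ryr2 and Kcne1), 0 at day 10 only, where fewer libraries are compared, and 25 in the 4 libraries; leaving out 1 gave 4 to 7. Hcn4, Kcne1, Ryr2 and Lyz2 passed in every such set. Cacna2d2 was lost without WT 4, WT 5, WT 6 or heterozygous 4, 5 or 6, and Scx without WT 1, WT 3, WT 5 or heterozygous 4 or 7. Lists by genotype (6) were 3 with no filter, 2 with the mitochondrial term, 0 with an estimated correlation and 0 with fry, and 1 to 7 with 1 library left out (1 without WT 2, 2 without heterozygous 7, 3 without heterozygous 4 or 5). The nodal list was called in each of these 12.

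Genes called by age (0) were 9 with a mean of at least 50, 206 with DESeq2, 16 at a threshold of 0.1, 13 with voom, 1 without WT 3 and heterozygous 7, 11 with the mitochondrial term and 1 in the 8 libraries; with 1 library left out there were 0 to 10 (10 without heterozygous 7). Listed genes past over their list alone by age (26) were 50 at a threshold of 0.1 and 42 with the mitochondrial term. That term kept 12 of the 26. It is mostly mitochondrial ribosomal RNA but also holds the reads of the mitochondrial genes, so it cannot judge these. With 1 library left out the count was 15 to 44 (15 without heterozygous 2, 17 without WT 3, heterozygous 4 or 6, 44 without heterozygous 7). Lists by age (4) were 13 with no filter, 7 with quantile normalisation, 10 with library weights, 8 at a threshold of 0.1, 8 without WT 3 and heterozygous 7, 10 with the mitochondrial term, 8 in the 8 libraries, 0 with an estimated correlation, 0 with the directional test of fry (1 with its mixed test) and 4 to 9 with 1 library left out (9 without WT 1 or heterozygous 7). The interaction (0) had 20 genes with DESeq2. Of the 9 mitochondrial genes past over their list alone in the interaction, 2 passed with quantile normalisation, 8 without heterozygous 7, and 0 in the 8 libraries, without WT 3 and heterozygous 7 together, without WT 4 or without heterozygous 3. With the mitochondrial term 0 of the 9 passed. That term is mostly mitochondrial ribosomal RNA but also holds their own reads. It therefore cannot tell a change of these genes from a change of the share. With no filter the median of all genes shifted by −0.17 by age and −0.15 in the interaction.

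The log2 difference by genotype reversed in the following cases. At day 8 only: Tbx3 0.075, mt-Cytb −0.22, mt-Atp8 −0.24, Hba-a1 −0.024, Aldh1a2 0.022 and the mitochondrial list mean −0.35. At day 10 only: Cd79a −0.21, Cd4 −0.59 and Cnp 0.10. Without WT 3 and heterozygous 7: Wt1 −0.29. In the 8 libraries: Cd79a −0.019, Hba-a1 −0.023 and the fibroblast list mean 0.046. In the 4 libraries: Tbx3 0.38, Cacna2d2 0.033, Slc8a1 0.12, mt-Cytb −0.32, mt-Atp8 −0.25, Pkp2 −0.0048, Oasl2 −0.046, Stard10 0.35, Vcan 0.15, Cx3cr1 −0.35, Stmn2 0.063, Wt1 −0.23, Fabp4 −0.25, and the means of the mitochondrial list −0.33 and the smooth muscle list −0.19, while the nodal list mean was −0.14 with camera in the other direction. With library weights the mitochondrial list mean was 9.91e-04, with camera in the other direction. With 1 library left out Cd4 ran from −0.26 to 1.02, Cd79a from −0.75 to 1.24, Hba-a1 from −0.057 to 0.45 and Hba-a2 from −0.0038 to 0.52.

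The titles share the numbers 2 to 6 across genotypes. Deviations of same-numbered libraries correlated between −0.157 and 0.108, 1 of 5 correlated best with its own number and 3 of the 5 pairs had the same age, so the numbers were not taken as pairs. With the number as a replicate block 0 genes were called by genotype and 0 by age, 2 genes passed over their list alone by genotype, 3 lists were called by genotype and 9 by age, and Hba-a2 (−0.028), Hba-a1 (−0.083) and the mean of the mitochondrial list (−0.032) reversed. None of the 9 mitochondrial genes passed in the interaction with this block. Depth limits the low genes: 3 reads are worth up to 5.19 normalised counts, so that Scx and Lmod1 rest on few reads. So do Gadd45b and Nefl, with wild-type means of 9.14 and 7.80. Hand1 was 3.04, 1.03 and 1.73 in heterozygous 4, 5 and 7. Rrm2, named by age, was 1.26 in WT 3, 6.84 in WT 4 and 8.65 in heterozygous 7.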

Other observations

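WT 5 was low both in Xist and in the Y-linked genes. Its Xist value was 60.8 normalised counts (58 reads), within the 57.8 to 354 of the 3 libraries with high Y-linked genes, while the other 8 libraries had at least 32214. The highest of its 4 Y-linked genes was Kdm5d at 14.7, against at least 590.3 for that gene in those 3 libraries. The median log2 difference of 431 X-linked genes from 10374 autosomal genes, each library against the other 11, was −0.02 in WT 5, inside the range of −0.10 to 0.09 in the others. It was 0.04, −0.08 and −0.04 in WT 1, WT 4 and heterozygous 4, the libraries with high Y-linked genes. The measure thus does not part the sexes and cannot tell the sex of WT 5. This library was kept in the main comparisons.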
